A study of Mus musculus with 6 samples.

How the data were processed

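Liver RNA of 21-day-old mice lacking the acyl-CoA binding protein ACBP, the product of Dbi, was compared with liver RNA of wild-type mice. Per the labels' protocols, the mice were fed until they were taken from their mother in the morning. Equal amounts of RNA from 5 mice were pooled for each array, so that 15 mice per genotype gave 3 pools per genotype and 6 arrays in all. Each pool holds other mice, so the spread between pools is that of pool means. Total RNA was extracted with Trizol and cleaned on columns, and biotin-labelled cRNA was hybridised to Affymetrix arrays. The submitters' processing notes name MAS5, an algorithm that turns the probes of a probe set into a signal and a detection call (Present, Marginal or Absent). Its version and settings are not given in the sources used here.

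The deposited workbook gives log2 signals, detection calls and detection p-values of 45101 probe sets per array. It also holds the authors' comparison of knockout with wild type: a p-value, a corrected p-value and an absolute fold change per probe set, without a direction. The deposited series matrix holds the log2 values again, with a largest difference of 4.91e-07 from the workbook, so the planned repeat with that table had nothing to differ and was not run. No probe-level files were used here, and a background correction other than that of MAS5 was not tried.

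The design planned to add 1 to linear signals before taking logarithms, and to use log2 values as such if the files held them. They did, so the deposited log2 values were used without a pseudocount or further normalization. The 64 control probe sets were left out, and probe sets called Present on at least 3 of the 6 arrays were kept, which left 22482. Dim signals of MAS5 vary widely on the log2 scale, so the values of probe sets near background are less precise, and the number of arrays limits the precision of all values.

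Gene names came from the platform annotation given with the data. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none. Entrez numbers of 34754 probe sets with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, and their symbols needed 0 updates. Probe sets with several symbols or none are not named. The RefSeq table also served to order genes along chromosomes. No coordinates are printed, because the files name no genome build.

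Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 22482 probe sets. A probe set was called changed at an adjusted p below 0.05. Every fold change is knockout minus wild type on the log2 scale, with its standard error from the moderated fit, and every adjusted p of a gene comes from this fit. For values per gene, the brightest tested probe set stood for the gene, and a probe set with the suffix _x_at, which can bind related transcripts, was taken last. This gave 10908 genes. With 3 pools against 3, an exact two-sided permutation test of a single gene cannot give a p below 0.1.

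The 37 gene lists were fixed before the data were examined. Of these, 35 had at least 3 tested members and were not the sex-chromosome list. They were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 35 lists. An estimated correlation and fry were the alternatives. The members of each list called over all probe sets were counted, and also those called when adjusted over the list alone.

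The genes named were set by a rule written before the data were examined. It takes Dbi first. It then takes the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol, groups that do not overlap and a mean signal of at least 100 in the higher group. It adds up to 5 members with the smallest p from each list past the threshold, up to 3 from each other list, the sex-chromosome genes and 12 genes chosen in advance. Some of these 12 are not reported here. Genes named outside the rule are said to be so. Of the 104 genes named by the rule that were called, 52 had more than 1 tested probe set. For 37 of them another probe set was called the same way and for 0 the opposite way. For the other 15 no other probe set was called, among them Ctse, Msmo1, Fads1, Slc22a5, Hspa5, Saa4 and Per2.

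The fit was tested on 5 simulated data sets drawn from the means and residual spread of the 22482 probe sets, each with 200 probe sets changed. Of the probe sets changed by 1.5-fold, 45.4% were called, of those changed by 2-fold 75.8% and of those changed by 4-fold 97.0%. Of all calls, 3.33% were unchanged probe sets. A simulated fall of the cholesterol list was found in 5 of 5 data sets. With no change, at most 1 list per data set passed, in data whose genes were drawn independently.

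Alternatives were a pseudocount of 16, no filter, Present on all 6 arrays, quantile normalization, median centring, no intensity trend, the pool number as a block, a plain two-sample test with equal variance, an added threshold of 1.5-fold, and leaving out each pool in turn. For the lists, an estimated correlation, fry and the mean of a gene's probe sets were added. A pseudocount of 1 and the Xist signal as a covariate were chosen after seeing the data.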

Results

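The transcriptome of the liver was measured in mice lacking ACBP, a small protein that binds acyl-CoA esters, and in wild-type mice, at 21 days of age. The 6 arrays fell into 3 pools of wild-type and 3 pools of knockout liver RNA, each from 5 mice. The share of probe sets called Present ran from 48.4% in knockout pool 3 to 51.1% in knockout pool 1. Median signals lay between 31.1 in knockout pool 1 and 33.4 in wild-type pool 2. The ratio of the 3' to the 5' control probe set of actin separated the genotypes, with 2.18 to 2.19 in wild-type and 2.34 to 2.35 in knockout pools, while that of Gapdh lay between 0.87 and 0.92 in all pools. The comparison asked how the liver transcriptome differed when ACBP was absent.

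Dbi, which encodes ACBP, was nearly absent from the knockout pools. Its brightest probe set read 15.94, 15.74 and 15.77 on the log2 scale in wild-type pools 1 to 3, the highest signal on each of those arrays. It read 5.37, 5.32 and 5.15 in the knockout pools, where only pool 2 was called Present. The mean fell by 10.54 on the log2 scale (SE 0.08, n = 3 pools per genotype, adjusted p = 2.27e-22), a size that background limits, with 2 of 3 knockout readings not called Present. The exact two-sided permutation p was 0.1, the smallest that 3 pools against 3 allow. The other 3 probe sets, all with the suffix _x_at, had log2 fold changes between -4.08 and -3.91 and were called Present in every knockout pool. Which part of the gene was deleted is not given in the sources used here, so the probe sets were not set against it.

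**Figure D1:**
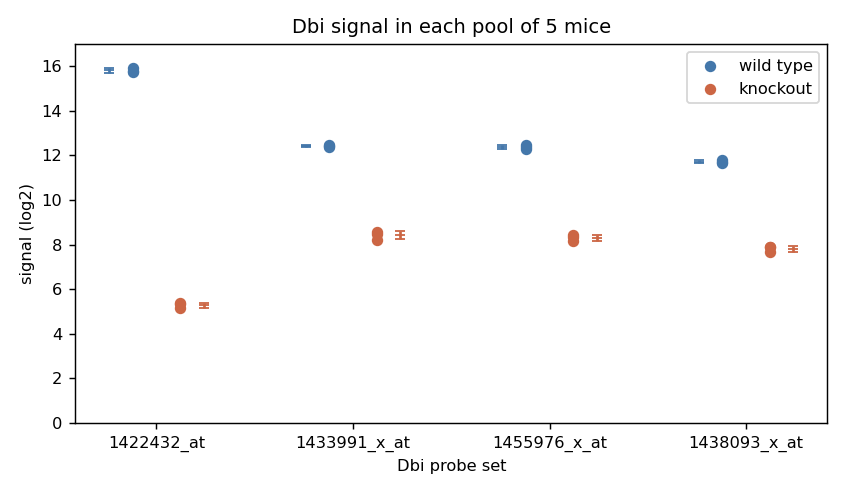
Signal of the 4 Dbi probe sets (horizontal axis) on the log2 scale (vertical axis) in each pool of 5 mice; points are pools, and the bars beside them give the mean and SD of 3 pools. The brightest probe set lies at 15.82 on average in wild type and at 5.28 in knockout, and the others stay between 7.67 and 8.57 in the knockout pools.

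Apart from Dbi, the 10 largest falls by the naming rule were all genes of sterol synthesis, and the rises were smaller except for that of Ctse. In all, 1277 of 22482 probe sets changed, of which 602 were higher and 675 lower in knockout liver. Of the changed probe sets, 202 differed by at least 2-fold, 28 of them higher and 174 lower. The 3 knockout pools lay apart from the 3 wild-type pools for 22.4% of tested probe sets, against 10% by chance. At an unadjusted p below 0.05 there were 3987 probe sets, against 1124.1 by chance. Taken 1 probe set per gene, 359 genes rose and 422 fell. The count moved with single pools: it was 639 without wild-type pool 1 and 3010 without knockout pool 3, and with these left out 265 and 2055 were higher. With the variance of each probe set estimated without the intensity trend it was 378, and with a plain two-sample test 30. In the authors' deposited table, 22 probe sets passed a corrected p of 0.05, among them the 4 of Dbi. Of these 22, 19 passed the detection filter and 17 were changed here.

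Ctse, which encodes the aspartic protease cathepsin E, rose by 5.84 (SE 0.13, adjusted p = 6.95e-15), from 4.46 ± 0.29 to 10.30 ± 0.14 (SD, n = 3 pools). Its second tested probe set read 7.30 in wild type and 7.13 in knockout (adjusted p = 0.547), so the probe sets of this gene disagreed. The other 9 of the largest rises lay between 1.17 and 1.47. They were Orm1 and Lcn2, which encode acute phase proteins, the acyl-CoA thioesterases Acot1 and Acot3, the nicotinamide methyltransferase Nnmt, the peptide-amidating enzyme Pam, the transferrin receptor Tfrc, the glutathione transferase Gsta2, and 3110009E18Rik. Orm1 rose by 1.47 (SE 0.15), Acot3 by 1.40 (SE 0.14), Nnmt by 1.33 (SE 0.12) and Tfrc by 1.24 (SE 0.09). Ctse, Pam and 3110009E18Rik lie 32, 22 and 1 tested genes from Dbi on the same chromosome in GRCm38.p6, as do Insig2 at 4 and Mcm6 at 16. A probe set unnamed here had a mean linear signal of 4.11 in wild type, where it was called Present on 1 of 3 arrays, and of 334.7 in knockout, where it was called on 3 of 3 (adjusted p = 1.04e-12).

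Transcripts of cholesterol synthesis enzymes fell together. All 17 tested members of the list of 20 were lower in knockout liver, both over all probe sets and when adjusted over the list alone, with a median log2 fold change of -2.53. Sqle, which encodes squalene epoxidase, fell by 5.48 (SE 0.24, adjusted p = 1.07e-10), from 11.01 ± 0.28 to 5.52 ± 0.75 (SD, n = 3 pools), and was called Present on 2 of 3 knockout arrays, as were Mvd and Mvk. Log2 fold changes were -3.91 (SE 0.16) in Idi1, -3.62 (SE 0.17) in Cyp51, -3.54 (SE 0.14) in Fdps and -3.41 (SE 0.12) in Msmo1, whose dimmer second probe set gave -1.30 (adjusted p = 0.115). Nsdhl, Mvd, Mvk, Hmgcs1 and Dhcr7 made up the rest of the 10 largest falls, with log2 fold changes from -3.34 to -2.53. For the whole list camera gave an adjusted p = 2.00e-57 at the preset correlation. With an estimated correlation the adjusted p = 0.174, and with fry it was 0.00523.

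**Figure D2:**
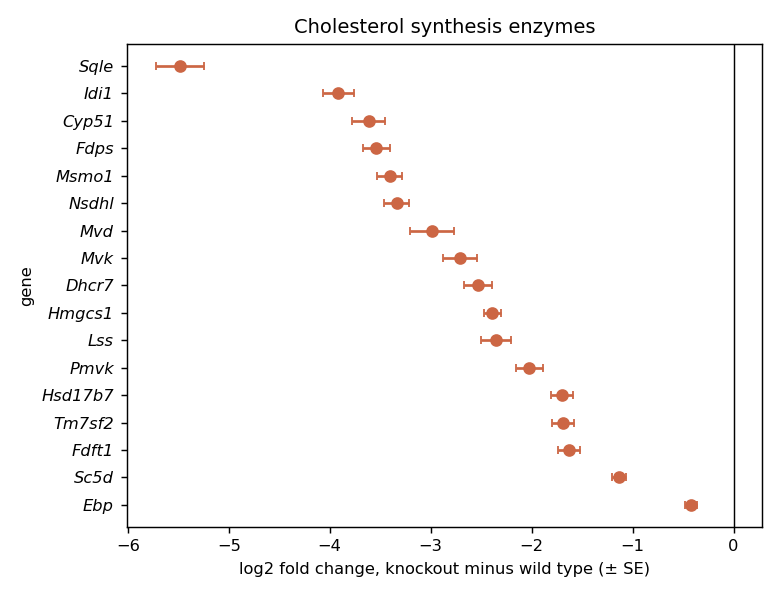
Log2 fold change, knockout minus wild type (horizontal axis), of the 17 tested cholesterol synthesis enzymes (vertical axis); points are the limma estimates from 3 pools per genotype and bars their standard errors. All lie below 0, with Sqle lowest at -5.48. Each gene is shown by its brightest probe set, so Hmgcs1 stands at -2.39 rather than at the -2.66 of the probe set with its largest fall.

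Genes that control sterol uptake and the SREBP transcription factors went both ways. Of 9 tested members, 5 fell and 2 rose, and adjusted over the list alone 5 fell and 3 rose. Srebf2, which encodes the factor best known for activating sterol synthesis genes, fell by 1.07 (SE 0.13). Stard4, a sterol carrier, fell by 0.88 (SE 0.10), Insig1 fell by 0.76 (SE 0.11) and Tmem97 fell by 0.72 (SE 0.09). Insig2 rose by 0.73 (SE 0.08) and Srebf1 by 0.44 (SE 0.08). Insig1 and Insig2 both encode proteins that hold back SREBP processing. The list as a whole was lower (adjusted p = 0.0451), but not with an estimated correlation (adjusted p = 0.448) or with fry (adjusted p = 0.0598), nor with quantile normalization (adjusted p = 0.0715).

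Of 17 tested genes of fatty acid synthesis and desaturation, 10 fell and 0 rose, and 13 fell when adjusted over the list alone. Log2 fold changes were -1.54 (SE 0.16) in the fatty acid elongase Elovl6, -1.49 (SE 0.13) in the fatty acid synthase Fasn, -1.46 (SE 0.11) in Acss2, -1.04 (SE 0.09) in Acly and -0.71 (SE 0.08) in the desaturase Fads1, whose second probe set gave -0.37 (adjusted p = 0.276). Scd1 read 11.61 ± 0.23 in wild type and 10.99 ± 0.87 in knockout (adjusted p = 0.215). The median log2 fold change was -0.58 (camera adjusted p = 1.17e-13). The estimated correlation gave adjusted p = 0.211, and with fry it was 0.0275.

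Cell cycle genes were also lower in knockout liver. Of 17 tested members, 16 fell, both over all probe sets and when adjusted over the list alone, and the median log2 fold change was -1.45. Log2 fold changes were -1.79 (SE 0.18) in Top2a, a DNA topoisomerase of dividing cells, -1.67 (SE 0.17) in the cyclin Ccna2, -1.60 (SE 0.16) in Birc5, called Present on 2 and 1 of 3 knockout arrays, -1.47 (SE 0.09) in the helicase subunit Mcm6 and -1.45 (SE 0.12) in the kinase Cdk1. Camera gave an adjusted p = 2.26e-29, an estimated correlation an adjusted p = 0.174 and fry an adjusted p = 0.00795. Of 9 tested genes of fetal and neonatal liver, 2 fell, with -0.56 (SE 0.15) in Afp and -0.43 (SE 0.11) in Mest, and the list did not pass (adjusted p = 0.0698).

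**Figure D3:**
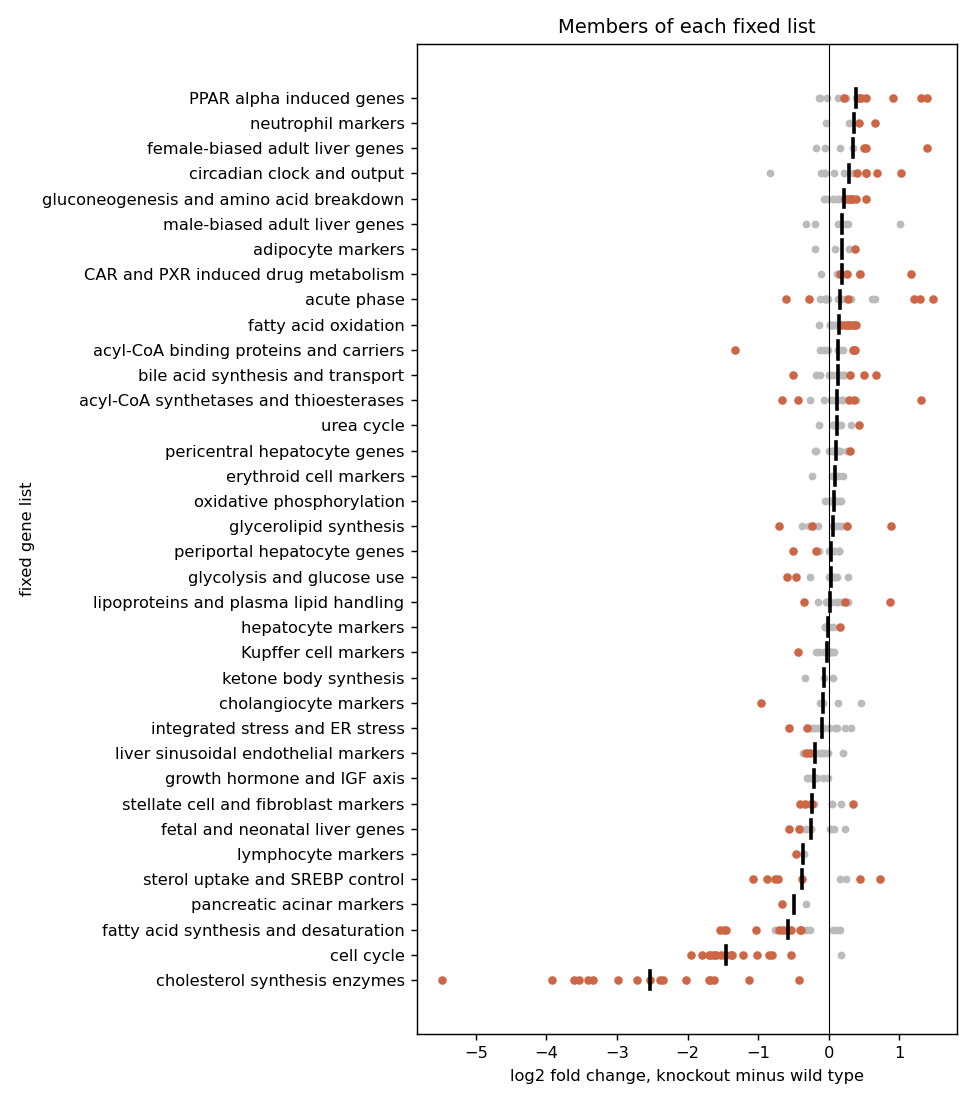
Log2 fold change, knockout minus wild type (horizontal axis), of each tested member of the fixed gene lists with tested members, the sex-chromosome list left out (vertical axis); coloured points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Cholesterol synthesis has the lowest median, -2.53, followed by the cell cycle with -1.45.

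Of 19 tested genes of fatty acid oxidation 7 rose and 0 fell, with Slc25a20, the carnitine carrier of mitochondria, up by 0.38 (SE 0.06), Cpt2 by 0.31 (SE 0.06), Acadm by 0.27 (SE 0.05) and Cpt1a by 0.24 (SE 0.06). Of 15 tested genes induced by PPAR alpha, a nuclear receptor activated by fatty acids, 7 rose and 0 fell. Acot1 rose by 1.30 (SE 0.12), Acot4 by 0.91 (SE 0.13) and Slc22a5 by 0.53 (SE 0.10), and Ppara itself by 0.39 (SE 0.08). Adjusted over the list alone, 10 members of the first list rose, and of the second 9 rose and 2 fell. Camera gave adjusted p = 3.89e-06 and 4.02e-06. Under an estimated correlation the adjusted p = 0.424 and 0.402, and with fry it was 0.0514 for both.

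Genes of gluconeogenesis and amino acid breakdown rose in 7 of 14 cases and fell in 0, among them Prodh by 0.52 (SE 0.07), Aass by 0.38 (SE 0.06) and Tdo2 by 0.33 (SE 0.04). Of 8 urea cycle genes, Asl alone rose, by 0.43 (SE 0.08). Of 12 tested drug metabolism genes induced by CAR and PXR, 4 rose, Gsta2 by 1.17 (SE 0.15) and Cyp3a13 by 0.44 (SE 0.08). Of 14 tested clock genes 5 rose, Usp2 by 1.02 (SE 0.14), Per2 by 0.68 (SE 0.12) and Dbp by 0.52 (SE 0.10), where the other 2 tested probe sets of Per2 were not called. Adjusted over the list alone, 8, 4, 6 and 8 members of these lists rose, and 1 clock gene fell. Their camera adjusted p were 2.30e-06, 0.00775, 1.21e-05 and 0.0013. When the correlation was estimated, the adjusted p = 0.424 for each of them.

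Of 16 genes of bile acid synthesis and transport, the sterol exporters Abcg5 and Abcg8 rose by 0.67 (SE 0.07) and 0.50 (SE 0.08) and Nr1h4 by 0.30 (SE 0.08), while Cyp8b1 fell by 0.51 (SE 0.14). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 10.80 ± 0.13 in wild type and 10.86 ± 0.07 in knockout (adjusted p = 0.784). Of 18 acute phase genes 4 rose and 2 fell: Orm1, Orm2, Lcn2 and Saa4 were higher, by 0.27 in Saa4 to 1.47 in Orm1, and Apcs fell by 0.28 (SE 0.06). Beside them, 2 of 4 tested neutrophil markers rose, S100a9 by 0.65 (SE 0.13) and S100a8 by 0.43 (SE 0.11). Of 7 tested female-biased liver genes 3 rose, Acot3, Cyp17a1 by 0.53 (SE 0.15) and Cyp2b13 by 0.50 (SE 0.13). These 3 were higher in every knockout pool than in every wild-type pool. They were highest in knockout pool 1, which stood apart at most Y-linked probe sets. Cyp17a1 read 9.09 in that pool, against 8.52 and 8.39 in knockout pools 2 and 3. Of the settings with all pools and the preset correlation, the list lost its call only without the intensity trend (adjusted p = 0.0574). It thus kept its call with the Xist signal as a covariate, which does not settle the part of pool sex. Camera adjusted p were 0.0329 for bile acid genes, 0.0341 for acute phase, 0.0225 for neutrophil markers and 0.00843 for female-biased genes. With an estimated correlation the adjusted p = 0.424, 0.439, 0.424 and 0.429. The bile acid and acute phase calls were also lost with quantile normalization, at adjusted p of 0.0604 and 0.0501. Adjusted over the list alone, 6 and 8 members of the first pair rose and 3 and 2 fell, and 3 neutrophil and 4 female-biased members rose.

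Oxidative phosphorylation (17 tested) and the growth hormone and IGF axis (10 tested) passed as lists with 0 members called. Their medians were 0.07 and -0.21, with camera adjusted p of 0.0341 and 0.000789. The estimated correlation gave adjusted p = 0.424 and 0.203, and fry 0.0808 and 0.0389. Adjusted over the list alone 0 and 2 members were called, both of the latter lower. Oxidative phosphorylation also failed to pass with quantile normalization (adjusted p = 0.0570), median centring (0.152), Present calls on all 6 arrays (0.0529), no intensity trend (0.129) and the pool number as a block (0.0653). Sinusoidal endothelial markers (2 of 12 fell, median -0.20), stellate cell and fibroblast markers (4 of 11 fell and Rgs5 rose by 0.35, median -0.24) and lymphocyte markers (1 of 3 fell) passed as lower, with adjusted p of 0.00203, 0.041 and 0.0326. Under an estimated correlation the adjusted p = 0.208, 0.424 and 0.402, and with fry 0.0255, 0.102 and 0.0474. Adjusted over the list alone, 4, 6 and 1 of these fell. The lymphocyte call was lost with quantile normalization (adjusted p = 0.0501). In all, 19 of 35 lists passed, 11 higher and 8 lower, and 0 passed with an estimated correlation, where 5 had an unadjusted p below 0.05. That correlation was estimated from 6 pools. Even the cholesterol list, with 17 of 17 members called, had an unadjusted p of 0.00747 there. A call lost in that setting therefore does not show that a list is unchanged. With fry 8 passed, 6 of these 19 and 2 others, glycolysis and glucose use as lower (adjusted p = 0.0151, though 2 of 9 fell, the median was 0.03 and camera gave 0.544) and adipocyte markers as higher (adjusted p = 0.0389, median 0.18). Of the 19 lists, 10 kept their call in each of 10 settings that kept all pools and the preset correlation. The 9 others, which lost it in at least 1, were sterol uptake, urea cycle, bile acid, acute phase, oxidative phosphorylation and female-biased genes and stellate cell, lymphocyte and neutrophil markers.

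The other 16 lists did not pass in the main setting. In the same 10 settings 5 of them gained a call at least once: acyl-CoA binding proteins and carriers (adjusted p = 0.0401) and acyl-CoA synthetases and thioesterases (0.0376) as higher without a filter, lipoproteins and plasma lipid handling as higher with quantile normalization (0.0460), fetal and neonatal liver genes as lower with Present calls on all 6 arrays (0.0447) and with the mean of a gene's probe sets (0.0492), and adipocyte markers as higher with that mean (0.00770). Hepatocyte markers had a median of -0.01, Kupffer cell markers one of -0.02 and erythroid markers one of 0.09, with 1 of 9, 1 of 12 and 0 of 6 tested members called, and as many when adjusted over the list alone. Within such lists, Fabp5, a fatty acid binding protein, fell by 1.33 (SE 0.11), Chpt1 rose by 0.89 (SE 0.08), Apoa4 rose by 0.87 (SE 0.12), Lpin1 fell by 0.71 (SE 0.14), Pgd fell by 0.59 (SE 0.11) and the endoplasmic reticulum chaperone Hspa5 fell by 0.31 (SE 0.07). Prom1, on the cholangiocyte list, fell by 0.96 (SE 0.16), and Cela1, on the pancreatic acinar list, which had too few tested members for a list test, fell by 0.66 (SE 0.11). Fabp4, an adipocyte marker, rose by 0.38 (SE 0.09).

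Signals of Y-linked genes differed between pools at most of their probe sets. The Y-linked gene Eif2s3y read 1.16 in knockout pool 1, where it was called Absent, and between 6.97 and 8.69 in the other 5 pools. The brighter probe set of Kdm5d read 2.29 there and 4.39 to 6.57 elsewhere. The probe sets of Uty disagreed: the dimmer read -0.55 there, called Absent, and 3.44 to 6.02 elsewhere, but the brighter read 5.87 there, called Present, and 5.65 to 6.33 elsewhere. Xist, expressed from the inactive X chromosome, read 11.14 in knockout pool 1 and between 9.04 and 11.04 in the others at its brightest probe set, lowest in knockout pool 3 and wild-type pool 2. Between genotypes Xist gave an exact two-sided permutation p of 0.9 and Eif2s3y one of 0.8. Without knockout pool 1 the count of changed probe sets was 1060, of which 373 were higher, and with the Xist signal as a covariate, chosen after seeing the data, it was 1561.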

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

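All tests of explanations in this part were chosen after the results had been seen.

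Signal in the control probe sets, which were left out of the comparison, was higher in every knockout pool than in every wild-type pool, with an adjusted p below 0.05, for 8 of the 58 that were called Present on all 6 arrays. A control probe set for the transferrin receptor was higher by 0.90. Of those for pyruvate carboxylase, 4 were higher by 0.36, 0.30, 0.26 and 0.26. Of those for Gapdh, 3 were higher by 0.22, 0.20 and 0.19. The adjusted p over the 64 control probe sets ran from 6.60e-05 to 0.0313. In the main comparison Tfrc, which encodes the transferrin receptor, rose by 1.24 and Pcx, which encodes pyruvate carboxylase, by 0.27 (adjusted p = 0.0204), the same way as these controls. The control probe sets for Dap, Phe, Thr and Lys, which are not among the 8, all read lowest in wild-type pool 1. A Dap probe set read 7.56 there and 8.34 to 8.53 in the other pools, and a Phe probe set read 3.96 and 5.14 to 5.33. A Thr probe set read 4.84 there and 5.83 to 6.15 elsewhere, and a Lys probe set read 3.84 and 4.73 to 5.13. No explanation was tested for the values of any control probe set, nor was their bearing on the comparison.

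Changed genes lay close to Dbi on its chromosome, in the gene order of GRCm38.p6. Among the 25 tested genes on each side 7 were changed, against a median of 3 around other genes, and 5.86% of windows elsewhere held as many. With members of the fixed lists not counted, 4 were changed and 35.1% of windows held as many. That width was set first. At 50 genes on each side there were 19, against 18 at most elsewhere (0% of windows as many), and at 100 there were 24 (1.31%). With list members not counted there were 16 (0.0230%) and 20 (1.53%). The values at 50 and 100 argue against chance clustering at those widths. The width set first does not, so the widths disagree and chance clustering is not settled. The requirement that all 3 widths agree was set after the value at 25 had been seen, and 10 windows and rings were computed in all. An effect of the targeted allele on adjacent genes alone would leave the ring from the 26th to the 100th gene without an excess. It held 17 changed genes, 6 higher and 11 lower, Ctse among them, and 3.40% of rings elsewhere held as many, without adjustment for the number of rings. The next ring, to the 200th gene, held 17 (16.9%). With chance clustering not settled, this excess decides nothing, and an effect on adjacent genes alone stays open too. DNA of another strain carried along with the targeted allele may also change neighbours in both directions, and this was not tested.

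The lists of cholesterol and fatty acid synthesis genes were lower, though not with an estimated correlation (adjusted p = 0.174 and 0.211), which could also follow from less milk taken before collection or from another hour of collection. Of 5 genes that rise in fasting (Pdk4, Pck1, Igfbp1, Angptl4 and Cpt1a), only Cpt1a was called higher and the median was 0.13. Igfbp1 stood at -0.24 (adjusted p = 0.0520), Pdk4 at -0.03, Pck1 at 0.14 and Angptl4 at 0.13. But the list induced by PPAR alpha, which fasting also raises, was higher (adjusted p = 4.02e-06, but 0.402 with an estimated correlation and 0.0514 with fry). Less milk therefore stays open. Of 8 clock output genes 4 were called higher (Dbp, Tef, Hlf and Per2) and 0 lower. Of these, Per2 lies 51 tested genes from Dbi, and its other tested probe sets were not called. Nr1d1 read 6.07 ± 0.14 in wild type and 5.97 ± 0.21 in knockout (adjusted p = 0.76). The core clock genes Arntl, Cry1 and Clock stood at -0.84, 0.53 and -0.07 and were not called (adjusted p = 0.0874, 0.0663 and 0.85). Another hour of collection therefore stays open too. An effect of lacking ACBP, which the design names, stays open beside both. Pdk4, Pck1, Angptl4, Nr1d1, Arntl, Cry1 and Clock are named here outside the naming rule.

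Cell cycle genes were lower, with a median of -1.45, though the list's call was lost with an estimated correlation (adjusted p = 0.174). An even loss of erythroid cells in the liver would take erythroid markers down by about as much. The median of the 6 tested, of 12 listed, was 0.085, with members between -0.24 and 0.20. Mean wild-type signals were 85.0 in Klf1 and 51.4 in Car1, where background can limit a fall. Alas2, at 514.3 in wild type, had more room and stood at -0.24 (adjusted p = 0.277). These values run against such an even loss as the whole cause without excluding it. Lymphocyte, stellate cell and fibroblast, and sinusoidal endothelial markers were lower as lists, with medians of -0.36, -0.24 and -0.20, though not with an estimated correlation (adjusted p = 0.402, 0.424 and 0.208). With fry their adjusted p were 0.0474, 0.102 and 0.0255. The stellate cell and fibroblast median and the endothelial median lie further from -1.45 than their members' spread (SD 0.24 and 0.16). That argues against an even loss of either cell type as the whole cause, while a part of it stays open. Fewer dividing cells within a cell type could leave its markers nearly unchanged, so these markers cannot decide on that. The lymphocyte median lies further off as well (SD 0.06), but only 3 of 12 listed markers were tested. Their mean signals ran from 37.4 to 86.4, where background can limit a fall, so fewer lymphocytes stay open as a cause. Pools of different sex make-up are argued against as the whole cause, since with the Xist signal as a covariate the median was -1.42 and without knockout pool 1 it was -1.59. These settings were not run with an estimated correlation. Of 9 tested genes of fetal and neonatal liver 2 were called lower and 0 higher, with a median of -0.25, but the list did not pass (adjusted p = 0.0698, and 0.448 with an estimated correlation). It passed as lower in 4 of 18 other settings and as higher in 0: with Present calls on all 6 arrays (0.0447), with the mean of a gene's probe sets (0.0492), without wild-type pool 3 (0.0427) and without knockout pool 1 (0.0353). Since the list did not pass in the main setting, it decides on neither, and both an earlier and a later stage of growth stay open. An effect of lacking ACBP stays open and untested.

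With 3 pools against 3 there are 10 splits, too few for a share below 0.05. The real split gave 1277 changed probe sets and the highest of the others 1, so 1 of 10 splits gave as many. It gave 19 shifted lists and the highest of the others 10, so 1 of 10 splits gave as many. Each other split mixes the genotypes, so their difference widens the spread within groups, and a part of it stays between groups. The counts of the other splits are therefore not those of data without a difference.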

How the results depend on the processing

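A pseudocount of 1 and the Xist covariate were chosen after seeing the data; the other settings were planned. The fall of Dbi at its brightest probe set passed in each setting in which it was tested. That probe set, though not the other 3, was left out where Present calls on all 6 arrays were required. Changed probe sets numbered 378 without the intensity trend (110 higher, 268 lower), 30 with the plain two-sample test (12 higher, 18 lower; 3268 at an unadjusted p below 0.05) and 476 with at least 1.5-fold (128 higher, 348 lower, by construction fewer). Leaving out 1 pool gave 639 to 3010 changed, 265 to 2055 higher and 374 to 955 lower. The lowest counts came without wild-type pool 1 and the highest without knockout pool 3, and the cause was not tested. Knockout pools 1 and 3 were the least alike within a genotype (correlation of log2 signals 0.9866), close to the highest value between genotypes, 0.9859. Quantile normalization gave 1697 changed probe sets and median centring 1685, both more than the main setting. Shifted lists numbered 12 without the trend, 8 with fry and 0 with an estimated correlation. There the medians of cholesterol synthesis (-2.53), fatty acid synthesis (-0.58) and cell cycle (-1.45) are as before, but the adjusted p were 0.174, 0.211 and 0.174; in all other settings run on them these 3 lists passed. Over pools left out, log2 fold changes of genes that were not called crossed 0: Cux2 -0.11 to 0.70, Ezr -0.21 to 0.00373, Camp -0.12 to 0.10 and Cyp7a1 -0.00549 to 0.13. Of the 104 named genes that were called, 4 were called in every setting run on them, and 68 were lost only with the plain test or without the trend. With the pool number as a block 1370 probe sets and 17 lists passed. Same-numbered pools did not deviate together (correlations from -0.08 to -0.00776), so the numbers do not pair the pools. Without a filter on dim probe sets 926 of 45037 were changed; the part of dim signals in this was not separated from that of the larger number of tests.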

Other observations

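Outside the fixed lists, further genes changed in knockout liver, and those named here were chosen after their values were seen. The log2 fold change was -2.26 (SE 0.19) in Aacs, which activates acetoacetate for lipid synthesis and was called Present on 5 of 6 arrays, and -2.21 (SE 0.13) in the retinol dehydrogenase Rdh11. Mmab, an enzyme of vitamin B12 metabolism, fell by 1.49 (SE 0.12) and the aldolase Aldoc fell by 1.44 (SE 0.11). Log2 fold changes were -1.76 (SE 0.12) in Pbk, -1.59 (SE 0.16) in Ube2c and -1.49 (SE 0.19) in Cdc20. Among the rises were G0s2, an inhibitor of triglyceride breakdown, by 1.08 (SE 0.15), Wfdc21 by 1.07 (SE 0.12), the monooxygenase Fmo5 by 1.03 (SE 0.08), the growth factor Nrg4 by 0.92 (SE 0.15) and the acyltransferase Gpat3 by 0.76 (SE 0.11).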
